A study of Homo sapiens with 4 samples.

How the data were processed

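Messenger RNA was measured in 4 libraries of RPE-1 cells, a human retinal pigment epithelial line immortalised with hTERT. Per the labels' protocols, RNA was extracted with TRIzol and strand-specific libraries were prepared from poly(A) RNA. Per the labels, 2 libraries came from untreated cells and 2 from cells given 400 nM aphidicolin for 7 h. The titles call the first group untreated, while its treatment label reads DMSO, so those cells may have received the solvent. Nothing in the labels says that the replicates came from separate cultures, so p-values of single genes measure only the spread between these libraries, which may be technical.

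The authors deposited 1 table of log2 values for 28027 genes. Raising 2 to each deposited log2 value and subtracting 1 gave values that summed to 10000000 in every library, so the deposited unit is log2 of 1 plus the reads per 10000000 (normalised reads below). Per the submitters' processing notes, TopHat2 2.1.1, DESeq2 and the hg19 build were named, with no role or order. The read counter, the annotation release and the strand setting are not given in the sources used here. The gene positions in the deposited table come with no named build. Of 27516 gene identifiers found in GENCODE release 29 on GRCh38, 25436 (92.4%) had identical start and end there, so positions are given as GRCh38. Because the strand setting is unknown, overlapping and antisense genes, and genes with near-identical copies such as histone genes, may share reads.

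In every library all values were whole multiples of the worth of 1 read, within a tolerance of 0.001 of a read. The recovered totals were 19364077 and 20483384 reads for untreated replicates 1 and 2, and 20285748 and 16004028 reads for aphidicolin replicates 1 and 2. A value of 3 reads, taken as the floor of detection, lay between 1.46 and 1.87 normalised reads. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.15 in the untreated pair and 5.46 in the aphidicolin pair, so each library was counted as 1 sample.

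Before the data were examined, the test, the filter, the gene lists, the rule for named genes and most alternatives were fixed. Genes with at least 10 normalised reads in at least 2 of the 4 libraries were kept, which left 12506. Values were put on the scale log2(value + 5), and all log2 changes and folds below are on that scale, which understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a variance trend, no replicate block, and two-sided p-values adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Only 2 residual degrees of freedom were available per gene, and the spread was shared across genes with 29.1 prior degrees of freedom. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so single genes were tested only in the limma model, which shares the spread across genes.

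In all, 21 gene lists were fixed, of which 20 had at least 5 tested members. These were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. With the preset, camera takes its degrees of freedom from the number of genes tested. Its p-values then reflect the spread across genes, not the spread between libraries, and a very small one is no measure of replication. With the estimated correlation 0 lists passed the threshold, and 1 had an unadjusted p under 0.05. That setting also leaves camera only the 2 residual degrees of freedom. A call lost there need not reflect correlation between genes. Estimates ran from -0.043 (replicative polymerase and primase list) to 0.768 (mitochondrially encoded list). The polymerase list lost its call although its estimate lay below the preset (camera adjusted p = 0.00426 with the preset and 0.281 with the estimate). Estimates above the preset were those of the G1/S (0.076), G2/M (0.039), p53 (0.054) and interferon (0.082) lists, among others. For such lists correlation between genes may also have cost the call. The rule for named genes took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose mean was at least 50 normalised reads, a panel of 17 genes named whatever their result, and up to 4 members of smallest p in each list with a call by camera or at least 3 called members, or up to 2 in the others. Members named outside this rule were chosen after their values were seen. List counts below cover tested members only. These were 8 of 30 listed histone genes, 12 of 21 NF-kB and secretory genes, 17 of 25 interferon-stimulated genes, 15 of 25 fragile site genes and 5 of 17 retinal markers.

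The fit was tested on simulated data drawn for the real genes at the real depths, with 200 genes changed. Of 12503 simulated genes tested, the share of changed genes recovered was 46% at 1.25-fold, 80% at 1.5-fold, 94% at 2-fold and 100% at 3-fold. Of 175 simulated calls 15 were false (8.57%), above the nominal rate. A simulated raised list was called, and 0 of 20 unchanged lists were. The simulated genes varied independently and shared a single dispersion (0.00197), estimated from well covered genes and used in both groups. The simulation therefore could not show false list or gene calls that arise from correlation between genes or from the noisier aphidicolin pair. The recovered and false shares hold for that setting and need not carry over to real genes of larger spread.

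Alternatives changed the pseudocount, the filter, the scaling (median-of-ratios or quantile), the variance trend, the replicate block, the threshold and the set test, and left out each library in turn. With 1 library left in a group, that library was assumed to vary like the other group. Chosen after seeing the data were limma's voom on the recovered reads, thinning to the shallowest library, and a pair of lists tested without the members they share with other lists. The planned count tests were not run, although the recovered reads would have allowed them. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reading and plotting.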

Results

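Gene expression was profiled by poly(A) RNA sequencing in RPE-1 cells with and without aphidicolin, an inhibitor of replicative DNA polymerases. There were 2 untreated and 2 aphidicolin libraries, with 19364077 and 20483384 reads in the untreated pair and 20285748 and 16004028 in the aphidicolin pair. Values are given as normalised reads, scaled to 10000000 per library. Across the 12506 genes tested, Pearson's r of log2 values was 0.998 between the untreated replicates and 0.996 between the aphidicolin replicates, and between 0.993 and 0.995 across groups. Genes are not independent replicates, and these correlations describe the libraries.

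The comparison asked which transcripts changed after 7 h in 400 nM aphidicolin, in a study about a replication checkpoint that involves FOXO transcription factors. With aphidicolin, 41 of 58 genes of a G1/S list rose and 2 fell, with the cyclin E genes CCNE2 and CCNE1 among the rises, and 66 of 70 genes of a G2/M list fell, among them those of the mitotic kinesin KIF20A and the mitotic kinase PLK1. Both lists were called by camera with its preset correlation but not with an estimated one (adjusted p = 0.281 for G1/S and adjusted p = 0.157 for G2/M with an estimated correlation). The estimated setting tests on 2 residual degrees of freedom, so a call lost there need not reflect correlation between genes. Both estimates lay above the preset of 0.01 (0.076 for G1/S and 0.039 for G2/M), so correlation may also have played a part. Rises also outnumbered falls among p53 targets (22 and 0 of 40), interferon-stimulated genes (7 and 0 of 17) and NF-kB-linked secretory genes (8 and 0 of 12). Those 3 list calls were lost in the same way (adjusted p = 0.281 for p53, adjusted p = 0.281 for interferon and adjusted p = 0.285 for NF-kB with an estimated correlation). In limma, 1333 genes were higher and 538 lower at an adjusted p under 0.05, with 2550 higher and 978 lower at an unadjusted p under 0.05. Most changes were small. The median size of a called log2 change was 0.36, and only 12 of the higher and 5 of the lower genes changed at least 2-fold.

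The groups did not overlap for 7057 genes (56.4%). For a single gene with exchangeable libraries the probability is 33.3%. All genes share the same libraries, so a shift common to a library can move the share, and the comparison is no test. The balance of calls depended on scaling. As deposited, 71.2% of calls were rises, while median-of-ratios scaling gave 811 higher and 870 lower genes (48.2% rises) and quantile normalization 691 and 638 (52.0%). The counts also depended on single libraries. Without untreated replicate 1 there were 289 higher and 186 lower genes, and without untreated replicate 2 there were 371 and 180. Leaving out aphidicolin replicate 1 gave 2738 and 1332, and leaving out aphidicolin replicate 2 gave 1850 and 907.

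**Figure D1:**
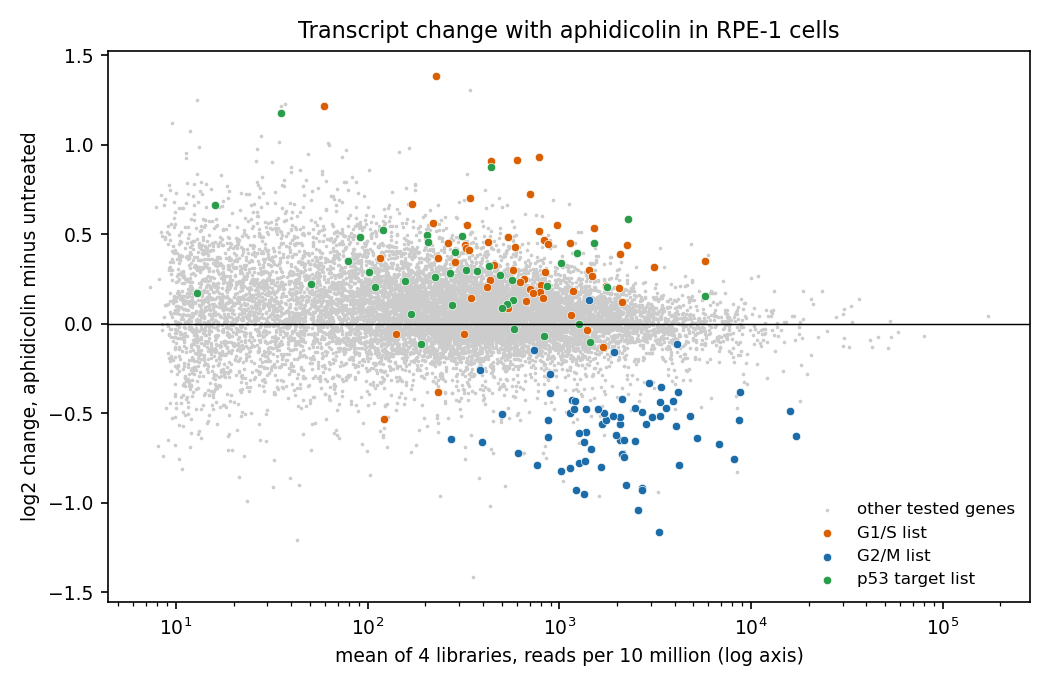
Each point is 1 of the 12506 tested genes, with the mean of the 4 libraries in normalised reads (per 10000000) on a log axis and the log2 change (aphidicolin minus untreated) on the vertical axis. Members of the G1/S list (orange) lie mostly above 0, with a median of 0.34, those of the G2/M list (blue) below 0, with a median of -0.56, and p53 targets (green) have a median of 0.28.

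Among called genes with a mean of at least 50 normalised reads whose groups did not overlap, CCNE2, which activates CDK2 at the entry into S phase, rose most (ENSG00000175305, chromosome 8, 94879770 to 94896678). Its level was 123.5 ± 8.93 (SD, n = 2) in untreated and 330.7 ± 26.3 (SD, n = 2) in aphidicolin libraries, a log2 change of 1.38 with a standard error of 0.099 and a limma adjusted p of 5.92e-12. FAM111B, a protease-like gene, rose from 195.3 ± 4.92 to 490.5 ± 7.03 (SD, n = 2 each), with a log2 change of 1.31. CCNE1 rose from 33.6 ± 3.64 to 84.5 ± 8.12 (SD, n = 2 each), with a log2 change of 1.21. The next largest rises among these genes were PLSCR4 at 1.01, SOX13 at 1.0, the ubiquitin ligase gene RNF144B at 0.98, the protocadherin gene PCDH9 at 0.97 and the intermediate filament gene SYNM at 0.96. Their deepest fall was that of TNFAIP8L1 (ENSG00000185361, chromosome 19, 4639518 to 4655568), from 516.0 ± 21.4 to 190.0 ± 1.81 (SD, n = 2 each), a log2 change of -1.42 with a standard error of 0.084 and a limma adjusted p of 1.58e-13. It was followed by KIF20A at -1.17, PLK1 at -1.04, NEURL1B at -1.02, the helicase gene PIF1 at -0.96, the spindle gene FAM83D at -0.96, GAS2L3 at -0.95 and NAV2 at -0.94. These 16 calls held in every refitted alternative.

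The G2/M list, which holds genes driven by FOXM1, B-MYB and the CHR element, fell almost as a whole. Each library pooled RNA over cells. For this list, the G1/S list and the lists below that hold cell cycle or replication genes, a change per cell cannot be told apart from a change in the share of cells in each cell cycle phase. The G2/M counts were as follows. Of its 70 tested members 66 fell, 0 rose and 4 did not pass, and 68 fell and 1 rose when adjusted over the list alone. The median log2 change was -0.56 (camera adjusted p = 7.66e-60; adjusted p = 0.157 with an estimated correlation; fry adjusted p = 0.00906). KIF20A (ENSG00000112984, chromosome 5, 138178719 to 138187715) fell from 4586 ± 164 to 2041 ± 84.2 (SD, n = 2 each). PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367) fell from 3480 ± 74.0 to 1688 ± 99.5 (SD, n = 2 each). CCNB1, the mitotic cyclin B1, fell from 3523 ± 93.2 to 1862 ± 1.84 (SD, n = 2 each), a log2 change of -0.92, and CDC20, an activator of the anaphase-promoting complex, had a log2 change of -0.93. CCNA2 (cyclin A2) fell by 0.56 and CDK1, the kinase that partners both cyclins, by 0.33 on the log2 scale. The CDK1 call was lost without untreated replicate 2 (log2 change -0.29, limma adjusted p = 0.128) and without a variance trend. The 4 members that did not pass were FOXM1 itself, at -0.12 (limma adjusted p = 0.196), CKAP2L at -0.16, AURKB at -0.15 and MELK at 0.13. The last 3 were named after their values were seen. FOXM1 was called lower with median-of-ratios scaling (log2 change -0.17, adjusted p = 0.0433) and without aphidicolin replicate 1 (log2 change -0.17, adjusted p = 0.000400), while its log2 change was -0.063 without aphidicolin replicate 2.

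The G1/S list of E2F targets and replication genes held mostly rises. Of its 58 members 41 rose, 2 fell and 15 did not pass, and 46 rose and 2 fell when adjusted over the list alone. The median log2 change was 0.34 (camera adjusted p = 2.16e-12; adjusted p = 0.281 with an estimated correlation; fry adjusted p = 0.0234). Besides the cyclin E genes, CLSPN, the adaptor for CHK1 activation, rose from 540.2 ± 31.4 to 1034 ± 89.5 (SD, n = 2 each), a log2 change of 0.93. The nuclease gene EXO1 rose by 0.91 and the chromatin remodeller gene HELLS by 0.91. E2F1 rose by 0.34 (limma adjusted p = 0.00623), a call lost without a variance trend and without either untreated library (adjusted p = 0.207 without replicate 1 and 0.133 without replicate 2). The members that fell were E2F2 at -0.53 and CDCA7 at -0.38, named after their values were seen.

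Lists of the replication machinery and its checkpoint came next. Of 12 replicative polymerase and primase subunits, the enzymes that aphidicolin acts on among them, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 change of 0.20 (camera adjusted p = 0.00426; adjusted p = 0.281 with an estimated correlation; fry adjusted p = 0.0372). The primase gene PRIM1 rose by 0.77, POLD3 by 0.52 and POLA2 by 0.47. Of 36 ATR-CHK1 checkpoint and fork protection genes, 14 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0122; adjusted p = 0.473 with an estimated correlation; fry adjusted p = 0.0765). CLSPN led the rises, and WEE1, which encodes the kinase that inhibits CDK1, fell from 1053 ± 51.8 to 680.4 ± 23.9 (SD, n = 2 each), a log2 change of -0.63. CHEK1 had a log2 change of 0.14 (limma adjusted p = 0.190). It was called higher without aphidicolin replicate 1 (log2 change 0.22, adjusted p = 0.00121), and its log2 change was 0.072 without aphidicolin replicate 2 and 0.087 with median-of-ratios scaling. The checkpoint list also lost its call without untreated replicate 1 (adjusted p = 0.0541), without aphidicolin replicate 2 (adjusted p = 0.0576) and without the 3 members it shares with the G1/S list (adjusted p = 0.0527), and its median was 0.11 with median-of-ratios scaling and 0.10 with quantile normalization. Of 8 tested histone genes, 2 fell and 0 rose (also 2 and 0 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.000473; adjusted p = 0.281 with an estimated correlation; fry adjusted p = 0.0704). Both calls, HIST2H2BF at -0.55 and H1F0 at -0.76, were lost with no filter (adjusted p = 0.0890 and 0.0758). The log2 change of H1F0 ranged from -1.14 to -0.37 over the alternatives. HIST2H2BF also lost its call without untreated replicate 2 (adjusted p = 0.261), which moved the list's median to -0.24, and H1F0 without aphidicolin replicate 1 (adjusted p = 0.0917). The list's median was -0.062 with no filter and -0.21 with a pseudocount of 20. Poly(A) selection captures few of the replication-dependent histone transcripts.

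**Figure D2:**
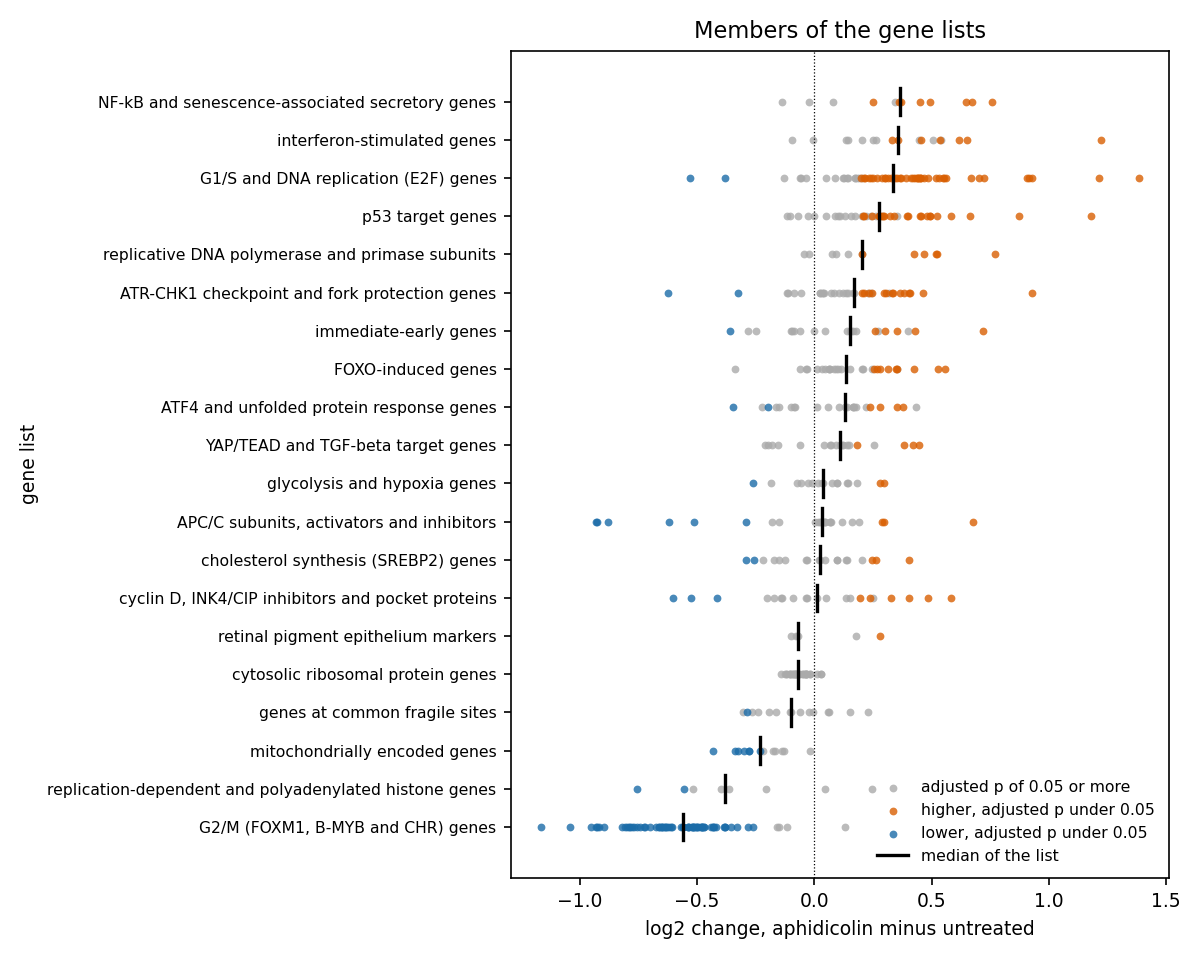
Each point is a tested member of 1 of 20 gene lists, placed by its log2 change (aphidicolin minus untreated) and coloured by whether it passed an adjusted p of 0.05, with a bar at the median of each list. In the G2/M list 66 of 70 members fell, and in the G1/S list 41 of 58 rose. Of the 32 ribosomal protein genes, 0 passed, against 4 lower with median-of-ratios scaling and 16 lower without aphidicolin replicate 1.

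Among the targets of p53, of 40 members 22 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 change of 0.28 (camera adjusted p = 7.50e-07; adjusted p = 0.281 with an estimated correlation; fry adjusted p = 0.0372). CDKN1A, the CDK inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), rose from 1826 ± 7.24 to 2744 ± 184 (SD, n = 2 each), a log2 change of 0.58 with a standard error of 0.061. MDM2, the ubiquitin ligase of p53, rose from 1279 ± 21.2 to 1752 ± 138 (SD, n = 2 each), a log2 change of 0.45. KITLG rose by 0.87 and the antiproliferative gene BTG2 by 1.18, the latter at a low level of 19.5 ± 1.35 in untreated and 51.1 ± 10.9 in aphidicolin libraries (SD, n = 2 each).

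Among genes known to be induced by FOXO factors, of 28 members 9 rose, 0 fell and 19 did not pass, with 10 rising when adjusted over the list alone, and the median log2 change was 0.13 (camera adjusted p = 0.0164; adjusted p = 0.328 with an estimated correlation; fry adjusted p = 0.0491). KLF2 rose from 255.6 ± 5.89 to 379.1 ± 30.7 (SD, n = 2 each), a log2 change of 0.56. CITED2 rose by 0.35 and SOD2, the mitochondrial superoxide dismutase gene, by 0.35. Both calls were lost without untreated replicate 1 (log2 changes 0.30 and 0.29) and without a variance trend. Over the alternatives the log2 change of CITED2 ranged from 0.22 to 0.48. The list lost its call without untreated replicate 1 (adjusted p = 0.0867) and without aphidicolin replicate 1 (adjusted p = 0.0593), and its median was 0.077 with median-of-ratios scaling and 0.083 with quantile normalization. The FOXO genes themselves did not pass. FOXO3 was at 683.5 ± 18.6 in untreated and 702.9 ± 12.5 in aphidicolin libraries (SD, n = 2 each), a log2 change of 0.04 with a standard error of 0.070 that turned to -0.018 with median-of-ratios scaling. FOXO1 had a log2 change of 0.35 (limma adjusted p = 0.276), at 10.8 ± 0.074 and 15.3 ± 2.13 (SD, n = 2 each), where depth may limit the test. Its log2 change was 0.46 with a pseudocount of 1 and 0.19 with a pseudocount of 20, without a call. FOXO4 was at 17.6 ± 0.012 and 18.2 ± 3.43 (SD, n = 2 each), with a log2 change of 0.03 (limma adjusted p = 0.940) that turned to -0.014 with median-of-ratios scaling, -0.066 with quantile normalization and -0.12 without aphidicolin replicate 2. CDKN1B, the CDK inhibitor p27 and a FOXO target, was at 1081 ± 33.4 and 1053 ± 21.3 (SD, n = 2 each).

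**Figure D3:**
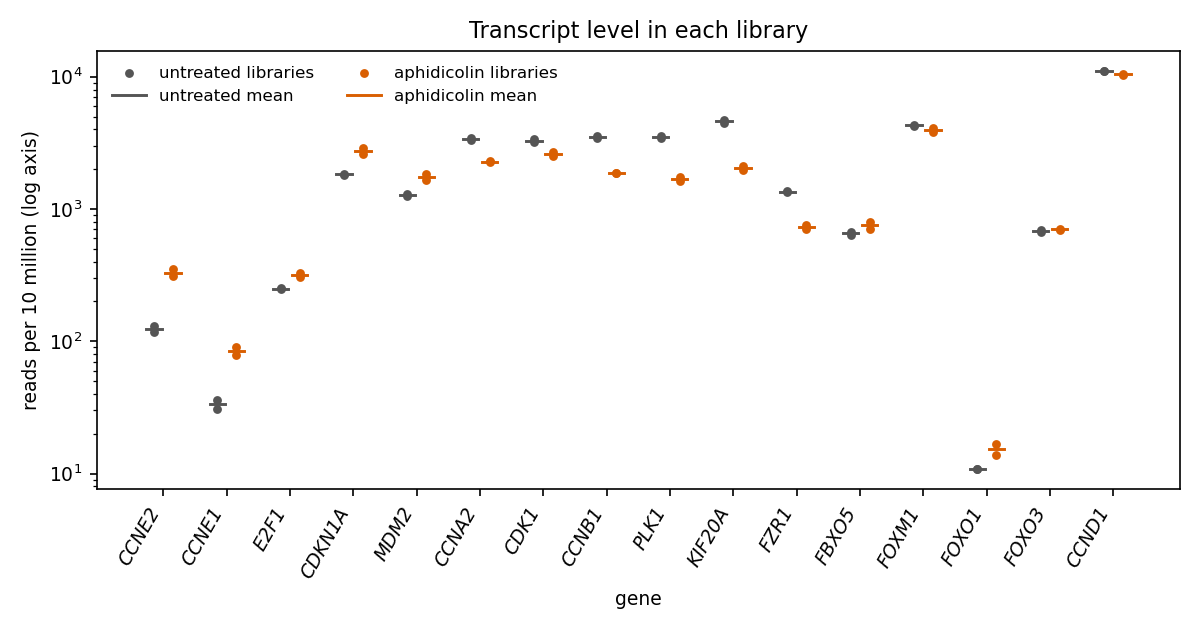
Levels of 16 genes in normalised reads (per 10000000), on a log axis, with 1 point per library and a line at the mean of each group (grey untreated, orange aphidicolin, n = 2 each). Both aphidicolin libraries lie above both untreated ones for CCNE2, CCNE1, E2F1, CDKN1A and MDM2, and below them for CCNA2, CDK1, CCNB1, PLK1, KIF20A and FZR1. They also lie above for FBXO5 and FOXO1 and below for FOXM1 and CCND1, none of which was called. The groups overlap for FOXO3.

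The anaphase-promoting complex list, which joins subunits, activators and inhibitors, was mixed. Of 24 members 6 fell and 3 rose (7 and 4 adjusted over the list alone). Its median log2 change was 0.03 and its mean -0.10. Camera, which compares a list with the other tested genes, gave the direction down (adjusted p = 0.0325, adjusted p = 0.328 with an estimated correlation, fry adjusted p = 0.0765). FZR1, which encodes the coactivator CDH1 (ENSG00000105325, chromosome 19, 3506273 to 3538330), fell from 1350 ± 18.4 to 731.0 ± 34.3 (SD, n = 2 each), a log2 change of -0.88 with a standard error of 0.066. FBXO5, which encodes the inhibitor EMI1, had a log2 change of 0.19 (limma adjusted p = 0.0754). It was called higher without aphidicolin replicate 1 (log2 change 0.28, adjusted p = 6.73e-06), and its log2 change was 0.10 without aphidicolin replicate 2. SKP2, which encodes a ubiquitin ligase subunit degraded through CDH1, rose by 0.68 and was named after its value was seen. UBE2S and UBE2C, the ubiquitin-conjugating enzymes of the complex, fell by 0.93 and 0.62. They, CDC20 and BUB1B are the 4 members shared with the G2/M list, and without them camera gave an adjusted p of 0.824. The call was also lost with no filter (adjusted p = 0.0781), with quantile normalization (adjusted p = 0.0880, median -0.018) and without aphidicolin replicate 1 (adjusted p = 0.315, median 0.054). The median turned to -0.022 with median-of-ratios scaling and -0.011 without aphidicolin replicate 2.

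Cyclin D genes, CDK inhibitors and pocket proteins showed no common direction, with 6 of 21 members higher and 3 lower (7 and 5 adjusted over the list alone) and a camera adjusted p of 0.509. The pocket protein gene RBL1 rose by 0.48 and CCND3 by 0.40. CDKN2C fell by 0.42, a call lost without untreated replicate 2 (adjusted p = 0.0744). CCND1 was at 11101 ± 6.92 and 10421 ± 149 (SD, n = 2 each), a log2 change of -0.09 (limma adjusted p = 0.317) that ranged from -0.15 to -0.036 over the alternatives, with no call.

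Of 12 NF-kB and secretory genes, 8 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 0.36 (camera adjusted p = 0.00315; adjusted p = 0.285 with an estimated correlation; fry adjusted p = 0.0526). TNFAIP3, a feedback inhibitor of NF-kB, rose by 0.65. CXCL8 rose by 0.76 and IL6 by 0.67. The CXCL8 call was lost without untreated replicate 2 (adjusted p = 0.112, log2 change 0.50) and without a variance trend, and the IL6 call with no filter (adjusted p = 0.0561). Of 17 interferon-stimulated genes, 7 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 2.18e-05; adjusted p = 0.281 with an estimated correlation; fry adjusted p = 0.0462). IFIT2 rose from 20.3 ± 3.10 to 53.9 ± 4.65, IFIT3 from 209.1 ± 2.27 to 305.6 ± 26.4 and IFI44 from 66.3 ± 4.77 to 106.9 ± 3.60 (SD, n = 2 each).

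Of 13 mitochondrially encoded genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 9.70e-06; adjusted p = 0.464 with an estimated correlation; fry adjusted p = 0.254). MT-CYB fell by 0.43, a call lost without untreated replicate 1 (adjusted p = 0.313, log2 change -0.23) and without a variance trend. Without untreated replicate 1 the list's median was -0.11, and without untreated replicate 2 it was -0.38. Of 32 cytosolic ribosomal protein genes 0 passed in limma, also when adjusted over the list alone, 0 passed with voom, and 2 were lower at an unadjusted p under 0.05, while 4 were called lower with median-of-ratios scaling and 16 without aphidicolin replicate 1, with a median of -0.071 (camera adjusted p = 0.000201; adjusted p = 0.470 with an estimated correlation; fry adjusted p = 0.199). That list's call was also lost with quantile normalization (adjusted p = 0.245, median -0.031), and its median was -0.13 with median-of-ratios scaling, -0.11 without aphidicolin replicate 1 and -0.033 without aphidicolin replicate 2. Of 15 genes at common fragile sites, very long genes prone to breakage under replication stress, 1 fell and 0 rose, also when adjusted over the list alone. The median was -0.099 (camera adjusted p = 0.0122; adjusted p = 0.285 with an estimated correlation; fry adjusted p = 0.153). The 1 called gene was EXOC4 at -0.29, whose call was lost without either untreated library (adjusted p = 0.245 without replicate 1 and 0.209 without replicate 2) and without a variance trend. The fragile site list also lost its call with no filter (adjusted p = 0.101, median -0.015) and without aphidicolin replicate 1 (adjusted p = 0.0977, median -0.066), and its median was -0.063 with a pseudocount of 20, -0.15 with median-of-ratios scaling and -0.16 with quantile normalization.

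The remaining lists did not pass with camera. Of 21 immediate-early genes 5 rose and 1 fell (adjusted p = 0.521), with the same numbers adjusted over the list alone. Of 23 ATF4 and unfolded protein response genes 4 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.782). Of 19 cholesterol synthesis genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.509), and of 17 glycolysis and hypoxia genes 2 rose and 1 fell, also over the list alone (adjusted p = 0.913). Of 19 YAP/TEAD and TGF-beta targets 4 rose and 0 fell (4 and 3 adjusted over the list alone; adjusted p = 0.509), led by CYR61 at 0.45 and CTGF at 0.42. Only 5 of 17 retinal pigment epithelium markers were tested, of which 1 rose and 0 fell (adjusted p = 0.782), also over the list alone. That gene was MITF at 0.28, with a range from 0.18 to 0.38 over the alternatives. Its call was lost without either untreated library (log2 change 0.30 without replicate 1 and 0.26 without replicate 2). The MITF call was also lost with no filter, with quantile normalization and without a variance trend. For the cyclin D, cholesterol and glycolysis lists camera's direction was down while the median and mean were above 0. Camera sets a list against the other tested genes, and the median log2 change of all tested genes was 0.053. The medians of the cyclin D, cholesterol and glycolysis lists all turned below 0 with median-of-ratios scaling. For the retinal list the median was -0.070 and the mean 0.042. The retinal median was -0.0040 without untreated replicate 1, -0.043 without aphidicolin replicate 1, -0.019 with quantile normalization and -0.13 with median-of-ratios scaling. Only 3 of 20 markers of other cell types (blood, neural, simple epithelium and muscle) were high enough to test, too few for camera, and 1 of them, SNAP25, rose by 0.47, from 51.4 ± 9.14 to 72.7 ± 2.38 (SD, n = 2 each). That call was lost without untreated replicate 2 (adjusted p = 0.471, log2 change 0.31), with no filter, with quantile normalization and without a variance trend.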

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

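The planned edgeR and DESeq2 tests, with and without a block, were not run. The deposited unit is log2, but whole reads were recovered, so leaving these tests out was a choice and not a limit of the data. The voom, thinning and shared-member tests were chosen after seeing the data. No gene called in the main test was called in the opposite direction under any refitted alternative. The pseudocounts of 1 and 20 and the filter of 50 kept both counts of calls within 1.5 times, as did voom on the recovered reads (1317 higher, 546 lower) and thinning to the shallowest library (903 and 402). With no filter 666 genes were higher and 334 lower, with 23660 genes tested. Median-of-ratios scaling gave 811 and 870, lowering the median log2 change of all genes from 0.053 to -0.0031, and the calls shared with the main test were 811 rises and all 538 falls. Quantile normalization gave 691 higher genes, and no variance trend gave 474 and 214. The cause was not tested for the last of these. An adjusted p under 0.01 gave 667 and 326, and at least a 2-fold change 12 and 5, by construction. Leaving out 1 library gave from 289 to 2738 higher and from 180 to 1332 lower genes. Fewer libraries were fitted, and the pair that remained set the spread: calls fell when it was the aphidicolin pair and rose when it was the untreated pair.

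With the replicate number as a block, 1267 genes were higher and 517 lower, and voom with the block gave 1326 and 525. The numbers share only a name here: the deviations of same-numbered libraries from their group means had a correlation across genes of -0.059 over 2 pairs, and no label pairs them. The block ended the calls of 2 named genes (NDRG1 and PFKFB4) and changed no list's call.

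With an estimated correlation camera called 0 lists, against 13 with the preset, and fry 6. The medians stay the same by construction with the estimated correlation: 0.336 for G1/S (adjusted p = 0.281), -0.561 for G2/M (0.157), 0.275 for p53 (0.281) and 0.135 for FOXO (0.328). Without 1 library the FOXO median ranged from 0.112 to 0.141. Medians that changed sign, all near 0 and with no cause tested, were those of the cyclin D list (-0.0103 with the filter of 50, -0.0458 with median-of-ratios, -0.0237 with quantile, -0.0336 thinned, and from -0.0580 to 0.0912 with 1 library left out), the APC/C list (-0.0217 with median-of-ratios, -0.0184 with quantile, and from -0.0112 to 0.0539 with 1 library left out), and with median-of-ratios the cholesterol (-0.0254) and glycolysis (-0.0222) lists, FOXO3 (-0.0177) and FOXO4 (-0.0138). FOXO4 was also at -0.0663 with quantile and ranged from -0.119 to 0.183 with 1 library left out.

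Of 101 named genes 81 were called, 0 of these reversed and 39 lost the call in at least 1 alternative, 33 of them with no variance trend, 29 without untreated replicate 1 and 27 without untreated replicate 2. Of the others 13 gained a call: 7 with median-of-ratios scaling, 11 without aphidicolin replicate 1 and 2 without aphidicolin replicate 2, some in more than 1 of these. Depth may limit the genes near 10 normalised reads, such as FOXO1 and H1F0. Thinning to the shallowest library cannot decide this, because it only removes reads and FOXO1 was already without a call. After thinning, FOXO1 stayed without a call (limma adjusted p = 0.274) and H1F0 kept its call.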

Other observations

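The genes in this paragraph and the next were chosen after their values were seen, as were the tests of the balance of calls and of mitochondrial share. The test of the slope between replicates was added after the other replicate test had come out, and its bound was written before its own value was seen. They were picked because they had changed, with no count of similar genes that had not, so they are examples and show no direction for any gene group. FAM111A, a protease that acts at stalled forks, rose from 870.5 ± 39.2 to 1390 ± 170 (SD, n = 2 each), a log2 change of 0.67 (limma adjusted p = 4.11e-08). The nuclease-helicase gene DNA2 rose by 0.70, the cohesin acetyltransferase gene ESCO2 by 0.65, WDHD1 by 0.61, the end-resection gene RBBP8 (CtIP) by 0.61, DONSON by 0.58 and the kinase gene CDC7 by 0.48. Falls outside the lists were those of SAPCD2 at -0.91, the spindle orientation gene GPSM2 at -0.75, INCENP at -0.67 and the citron kinase gene CIT at -0.65. ARL6IP1, an abundant transcript, fell from 10864 ± 224 to 6116 ± 301 (SD, n = 2 each).

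Some single genes with known immune functions were picked in the same way. CIITA, the master regulator of MHC class II, rose from 32.3 ± 7.67 to 66.0 ± 1.46 (SD, n = 2 each), a log2 change of 0.95 (limma adjusted p = 6.68e-05). APOL6 rose by 0.78, DTX3L by 0.65, TLR4 by 0.49, CD274, which encodes the checkpoint ligand PD-L1, by 0.48 and PARP14 by 0.48.

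Genes spanning at least 200 kb fell more often than shorter ones. Of 919 such genes 85 fell (9.25%), against 453 of 11587 shorter genes (3.91%), and the share reached 12.8% over 400 kb; NAV2, at 771 kb, was among the deepest falls. With expression level, transcript length and GC content as linear terms in a logistic model, the odds ratio of a fall was 2.77, with a lower 95% bound of 2.14. These linear terms did not account for the excess of falls. The model treated genes as independent, so its bound is too narrow, and it could not exclude a dependence of another shape. Among long genes the log2 change fell with log2 span, with a slope of -0.080 and an upper bound of -0.056. Slopes between replicates reached only 0.154 of its size, which argues against a slope of that size between libraries of the same group. A slope shared by both libraries of a group, apart from the treatment, could not show there and stays open. A span offset between libraries also stays open, since the long-minus-shorter median was -0.056 between groups and up to 0.567 of that size between replicates. As deposited, the median log2 change was -0.00040 in long and 0.056 in shorter genes. The typical long gene thus did not fall, though this depends on the scaling. Long genes also rose less often (7.51% against 10.9%). The long-minus-shorter median was -0.047 without untreated replicate 1 and -0.062 without untreated replicate 2. It was -0.035 without aphidicolin replicate 1 and -0.075 without aphidicolin replicate 2. The shares of long and shorter genes that fell lay closer together on leaving out any library except aphidicolin replicate 2. With median-of-ratios scaling they were 14.7% and 6.34%. That aphidicolin may lower transcripts in proportion to gene span is therefore a hypothesis only.

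More genes rose than fell as deposited (71.2% of calls). With median-of-ratios scaling rises were 48.2% of calls, but that scaling centres the changes by construction (median log2 change -0.0031, against 0.053 as deposited), so a near-even balance would follow whether or not the excess is real. An offset from the scaling to 10000000 reads and a real excess of rises under aphidicolin cannot be told apart here, because no outside standard for the amount of RNA was used.

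Of 13 mitochondrially encoded transcripts 7 fell and 6 did not pass, with the list's call lost with an estimated correlation (adjusted p = 0.464) and with fry (adjusted p = 0.254). Their share of reads was 2.41% ± 0.249 in untreated and 2.07% ± 0.108 in aphidicolin libraries (SD, n = 2 each). The untreated replicates differed by 0.352 percentage points, as much as the group means did (0.347). A difference between libraries apart from the treatment may therefore account for it, and an effect of aphidicolin stays open.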
